A study of Mus musculus with 20 samples.

How the data were processed

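The libraries were made from brain of mice of 4 genotypes, with 5 libraries per genotype and 20 in all. Total RNA was extracted from a single hemisphere of each brain and polyadenylated RNA was sequenced, per the labels' protocols. The genotypes were wild type (WT), knockout of Glb1 (Glb1KO), knockout of Neu3 (Neu3KO) and knockout of Glb1 and Neu3 together (DKO). Genotype and replicate number were taken from the labels. Ages were not given in the sources used here. The labels did not state that each library came from a separate animal, although each carried its own animal identifier. The p-values therefore measured the spread between these libraries.

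The authors deposited a table of raw read counts per gene, with 1 column per library and no normalization. The submitters' processing notes named fastp, HISAT2 2.0.5, featureCounts 1.5.0-p3 and DESeq2 1.20.0, and the builds mm10 and GRCm38. They gave no roles, order, strand setting or filters. Reads shared by near-identical copies such as Lilr4b and Lilrb4a, Iltifb and its paralog, C4b and C4a, or the H2 genes could therefore have been split or lost. Antisense partners could not be separated from their genes either. Gene coordinates are those of the deposited table. Of its 54532 gene identifiers, 54409 occurred in GENCODE M21, and 53499 had the same start and end there. The authors also deposited their own comparison of DKO with WT, whose log2 fold changes and p-values are described per the file headers. The FPKM table of the same libraries was not used here, since its counts were tested directly. All sample columns of the count table matched a library, and no row lacked a gene name.

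Total counts per library ran from 15162311 to 25145806. Of the genes in the table, 18336 were kept by the edgeR filter for low counts and tested. All 20 libraries entered a fit with a mean per genotype, so that the groups shared an estimate of the spread. The tools were R 4.3.3, edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0. Counts were scaled with TMM factors, and edgeR's robust quasi-likelihood F test was used with Benjamini-Hochberg adjustment at 0.05 and no fold minimum. Standard errors (SE) of log2 fold changes were derived from the F statistic. CPM values were TMM-scaled. The interaction of the knockouts was the DKO minus Glb1KO difference less the Neu3KO minus WT difference.

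Before the data were examined, 36 gene lists were fixed, covering brain cell types, neighbouring tissues and pathways. Their members were tested as sets with camera in limma, on log2 CPM with a prior count of 2 and a preset correlation of 0.01, two-sided, with adjustment over all lists and comparisons. The same test was repeated with the correlation estimated for each list, and fry was run beside it. A score per library was the mean over members of log2 CPM less the WT mean, compared between genotypes with exact two-sided permutation tests over 252 arrangements, for which the smallest p is 0.00794. The rule for genes named in the text was also fixed then. It took the 10 highest and 10 lowest fold changes in the comparisons of DKO and Glb1KO with WT, and 5 and 5 in the others. These genes had an adjusted p under 0.05, a mean of at least 1 CPM, no overlap between groups (not asked of the interaction) and a protein-coding annotation. Genes within 20 Mb of Glb1 or Neu3, Y-linked genes, Xist and unnamed gene models were left to a separate paragraph or left out. From each list the rule added up to 4 members with the smallest adjusted p and up to 2 with the highest CPM.

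Folds against a group with no reads were computed against 3 reads over the group. Such floors and the 95% intervals of ratios cover counting error only. The methods were tested on simulated counts with the real means, library sizes and dispersions. For DKO vs WT, with 18067 genes tested, the 1.5-fold changes were recovered in 55.4% of genes, the 2-fold changes in 81.2% and the 4-fold changes in 100%, with 10 false calls among 162. For Neu3KO vs WT, with 18065 genes tested, the corresponding shares were 67.2%, 78.5% and 98.5%, with 8 false calls among 169. A simulated list of 20 genes raised 1.5-fold was called in each comparison, and none of 35 unchanged lists was. The simulated genes varied independently, so this did not test the preset correlation on lists of correlated genes. Alternatives tried were other scaling factors, 2 other filters, DESeq2, fits of the compared groups alone, the replicate number or the identifier letter as a term, a fold minimum, the removal of genes near the targeted genes and of each library in turn. Fits restricted to libraries whose identifiers began with the same letter were added after the data were seen. A term for sex was planned, but all 20 libraries lacked reads of Ddx3y, Uty, Kdm5d and Eif2s3y on the Y chromosome, so it could not be fitted.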

Results

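RNA from a brain hemisphere was sequenced in mice of 4 genotypes, with 5 libraries each: WT, Glb1KO, Neu3KO and DKO. Glb1 codes for the lysosomal beta-galactosidase that cleaves GM1 ganglioside, and its loss causes GM1 gangliosidosis. Neu3 codes for a sialidase of the plasma membrane that acts on gangliosides. Total counts ran from 16649633 to 19212266 in WT, from 15734414 to 20391893 in Glb1KO, from 15162311 to 25145806 in Neu3KO and from 16682458 to 18525446 in DKO. The first principal component held 28.4% of the variance and placed the WT libraries between -31.1 and -20.3, the Neu3KO libraries between -21.9 and -13.8, the Glb1KO libraries between -3.4 and 2.6 and the DKO libraries between 35.5 and 49.8. Each library had Xist reads, from 928.1 to 1293 CPM, and none had reads of the male transcripts Ddx3y, Uty, Kdm5d and Eif2s3y. The animal identifiers began with E in all WT libraries, in 2 Glb1KO, 1 Neu3KO and 2 DKO libraries, with L in 3 Glb1KO libraries, and with W in 4 Neu3KO and 3 DKO libraries. The meaning of these letters was not given.

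The targeted genes were measured first, as a test of the genotype labels. Glb1 (ENSMUSG00000045594, GRCm38 chromosome 9, from 114401076 to 114474898) was at 20.2 ± 1.32 CPM in WT (SD, n = 5) and at 3.38 ± 0.903 CPM in Glb1KO (SD, n = 5), or 16.7% of WT, with an exact permutation p = 0.00794. In DKO it was at 19.8% of WT, with the same exact permutation p = 0.00794, and in Neu3KO at 102%. Neu3 (ENSMUSG00000035239, chromosome 7, from 99811439 to 99828417) was at 3.85 ± 1.22 CPM in WT (SD, n = 5), at 74.4% of WT in Neu3KO and at 77.4% in DKO. Neither difference in Neu3 passed the test, with an exact permutation p = 0.159 for Neu3KO and an exact permutation p = 0.23 for DKO. Over the 10 libraries labelled as lacking Neu3, its mean was 2.92 CPM, against 3.95 CPM in the 10 others (permutation p = 0.0105, chosen after the values were seen). Gene-level counts therefore separated the Glb1 labels completely and the Neu3 labels only weakly.

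**Figure D1:**
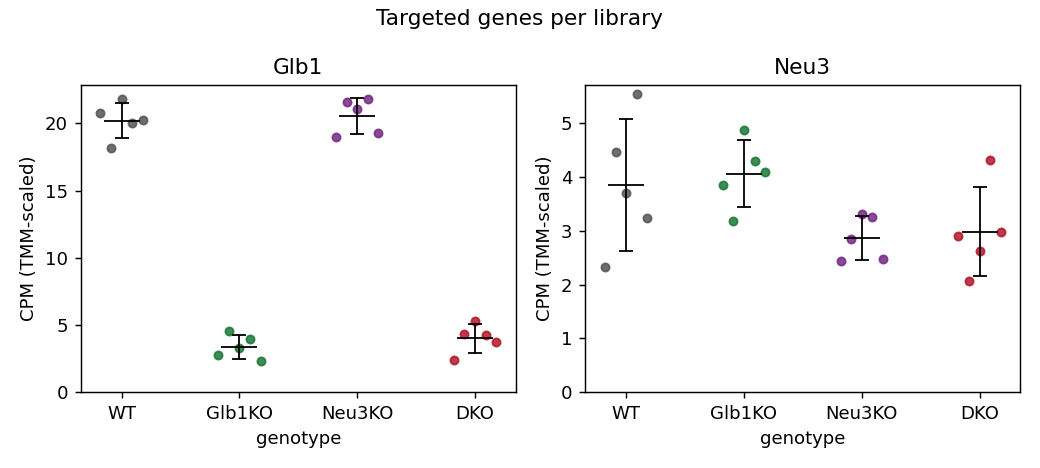
TMM-scaled CPM of Glb1 and Neu3 (vertical axes) in each library by genotype (horizontal axes), with the mean and SD of 5 libraries as bars. Glb1 sits at 20.2 CPM in WT and 3.38 CPM in Glb1KO on average, while the Neu3 values of the genotypes overlap.

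DKO was compared with WT, the comparison that the series design names. Genes of activated microglia, the resident macrophages of brain, were far higher in DKO: Gpnmb was raised 131-fold (log2 7.04, SE 0.15, n = 5 per group), Cst7 119-fold, Itgax 64-fold, Lilr4b 88.7-fold and Cd22 51.4-fold. Lcn2, a secreted protein of reactive astrocytes, was raised 92.1-fold, a size that rested on 20 reads over the 5 WT libraries. Atp6v0d2, a subunit of the vacuolar proton pump, had no reads in WT and was at least 125-fold higher in DKO against a floor of 3 reads over the group. Lilrb4a, Stra6l and Ly9 were raised 60.9-, 48.1- and 38.4-fold. The lowest folds were those of Hoxb5 (log2 -2.87, SE 1, adjusted p = 0.0409), the myelin gene Opalin (log2 -2.33, SE 0.22), Abhd12b (-1.99), Alpk2 (-1.74), Colq (-1.67), Iltifb (-1.53) and the activity-induced genes Npas4 (-1.73), Egr2 (-1.71), Arc (-1.57) and Nr4a1 (-1.43). Hoxb5 is a member of the hindbrain and spinal neuron list, whose score was -1.23 in DKO. In all, 5323 of 18336 genes passed the threshold, with 2558 higher and 2765 lower. Of these, 782 changed at least 2-fold, with 621 higher and 161 lower. With the identifier letter as a term the count was 3363, and among libraries with identifiers starting with E, of which DKO had 2, it was 2370. Among the latter Gpnmb was at 6.96, Lcn2 at 5.56 and Opalin at -1.87. Hoxb5 was called among the latter (-3.93, adjusted p = 3.09e-05), but its call was lost with the letter term (-2.48, adjusted p = 0.17), with DESeq2, without the filter, and without any of WT replicates 2 to 5 or DKO replicates 1 to 4.

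All 23 measured genes of the disease-associated microglia list rose in DKO, with a median log2 change of 2.20. They included Cd68 (3.89, SE 0.11), Clec7a (7.22, SE 0.27), the receptor gene Trem2 (2.87, SE 0.10), Ctsz (2.18) and Apoe (1.29). Of the homeostatic microglia genes, 8 of 14 rose and 1 fell, with P2ry13 at 1.29 and Csf1r at 0.63, and the list's adjusted p = 0.181 with an estimated correlation. Reactive astrocyte genes rose in 17 of 18 cases, with Serpina3n at 4.84 (SE 0.11), Gfap at 4.36 (SE 0.14), Osmr at 3.69 and Cd44 at 2.72. Of 45 lysosome genes 38 rose, among them Grn (1.98, SE 0.06), Laptm5 (2.12) and Ctsb (1.29). Complement genes rose in 11 of 12 cases, with C4b at 3.79 (SE 0.07) and C1qa at 2.62. Type I interferon response genes rose in 19 of 23 cases, with Ifit3 at 1.46 and Bst2 at 1.53. Of 16 antigen presentation genes 10 rose and 1 fell, with B2m at 1.80 and H2-K1 at 1.67. Cytokine and chemokine genes rose in 10 of 12 measured cases, with Ccl3 at 4.14 and Cxcl16 at 1.95, and Il33 was called at -0.27, a direction that was lost among libraries starting with E (0.018). That list had 22 members, and Tnf, Il1b, Il6 and Ccl5 were among those too low to test. Ganglioside breakdown genes rose in 11 of 18 cases and fell in 2, with Hexa at 1.16 and Ctsa at 1.15. Adjusted over the list alone, the counts were 23, 18, 40, 11, 21, 13, 11 and 13 called genes for the microglia, astrocyte, lysosome, complement, interferon, antigen, cytokine and breakdown lists.

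Myelin and mature oligodendrocyte genes fell in 18 of 19 cases in DKO, with Fa2h at -1.34 (SE 0.11), Mag at -0.94, Tspan2 at -0.86 and Mbp at -0.44. Among oligodendrocyte precursor genes 5 of 13 fell, with Sox10 at -0.82, Olig2 at -0.77 and Olig1 at -0.57, and the list did not pass its test (adjusted p = 0.0961). Activity-induced immediate early genes fell in 12 of 13 cases, with Egr1 at -1.27, and the list's adjusted p = 0.079 with an estimated correlation. Their score was below WT in all knockout groups, at -1.157 in DKO, -0.441 in Glb1KO (exact p = 0.0397, adjusted exact p = 0.0841) and -0.387 in Neu3KO. A shift in the WT libraries was not separated from genotype. The DKO score was also lower than that of Glb1KO by 0.716 (exact p = 0.0238) and of Neu3KO by 0.77 (exact p = 0.00794). Pan-neuronal genes fell in 8 of 14 cases, with Nefm at -0.69 and Vsnl1 at -0.36, and the adjusted p = 0.131 with an estimated correlation. Synaptic genes fell in 12 of 21 cases, with Shank3 at -0.45 and Syn1 at -0.38 (adjusted p = 0.125 with an estimated correlation). Cerebellar neuron genes fell in 5 of 11 cases, with Itpr1 at -0.74, Car8 at -1.29 and Pcp2 at -1.02 (adjusted p = 0.486 with an estimated correlation). With the preset correlation, 23 of 36 lists passed the threshold in DKO vs WT. With an estimated correlation 11 did, namely those of disease-associated microglia, reactive astrocytes, lysosome, complement, interferon, cytokines, ganglioside breakdown, antigen presentation, border-associated macrophages, apoptosis and p53 targets, and myelin. No called list differed in sign between its median, mean and test. The authors' deposited comparison held 5041 genes at an adjusted p under 0.05, of which 4791 were also called here, with 0 in the opposite direction.

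**Figure D2:**
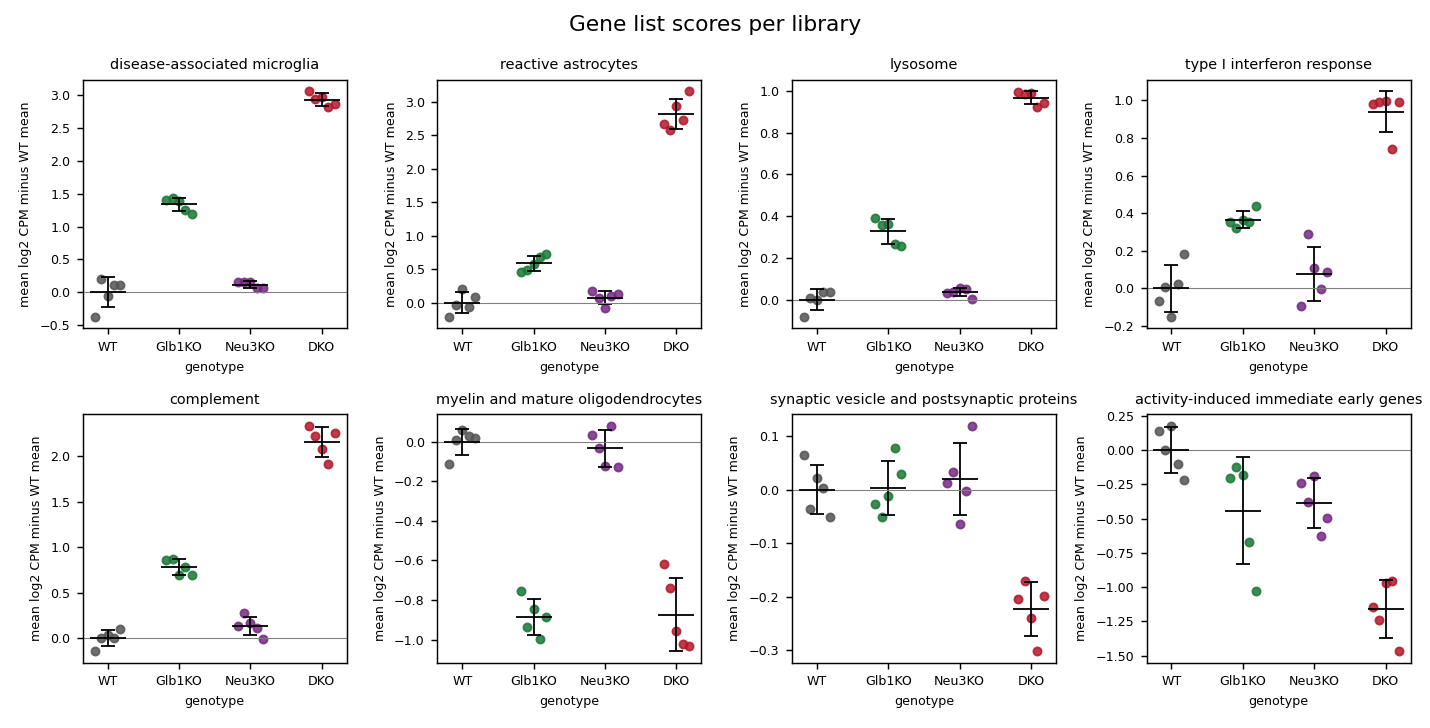
Mean log2 CPM of the members of 8 gene lists over the WT mean (vertical axes) per library by genotype, with the mean and SD of 5 libraries as bars. The disease-associated microglia score averages 1.34 in Glb1KO and 2.93 in DKO, while the myelin score averages -0.88 in Glb1KO and -0.87 in DKO.

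Glb1KO was compared with WT, for the effect of losing Glb1 alone. Microglial genes were raised by less than in DKO: Cst7 was raised 19.4-fold (log2 4.28, SE 0.39, n = 5 per group), Itgax 14-fold, Cd22 12.9-fold, Gpnmb 11-fold, Ly9 10.3-fold, Lilrb4a 10.2-fold, Lilr4b 7.71-fold and the lysozyme gene Lyz2 7.23-fold. Of the lists, that of myelin had the most members that were lower, 18 of 19, with Opalin at -1.57 (SE 0.20), Mal at -1.19, Fa2h at -1.09, Myrf, a transcription factor of myelination, at -1.08 (SE 0.07), Tspan2 at -0.99 and Mbp at -0.70. Erbb3 (-1.25), Abca8a (-1.12), Galnt6 (-1.07) and Ankub1 (-1.20) were also lower, as were Slc6a5 (-1.48) and Glra1 (-1.29), genes of glycine transmission. Slc6a5 is a member of the hindbrain and spinal neuron list, whose score was -1.66 in Glb1KO. A smaller share of hindbrain tissue therefore stayed open for its fall. In all, 726 genes passed the threshold, 321 higher and 405 lower. Of these, 99 changed at least 2-fold, with 60 higher and 39 lower. With the identifier letter as a term the count was 315, and among libraries with identifiers starting with E, of which Glb1KO had 2, it was 291. Among the latter Cst7 was at 4.08 and Opalin at -2.09. Stra6l (2.12, adjusted p = 0.035), Slc6a5, Glra1, Ankub1 and Ms4a7 (2.09) lost their call with the letter term, where they were at 1.43, -1.28, -1.22, -1.12 and 1.45 on the log2 scale. Among the libraries starting with E, Slc6a5 (-1.29, adjusted p = 0.0126) and Glra1 (-1.22, adjusted p = 0.00153) were called, and Stra6l (1.42, adjusted p = 0.741), Ms4a7 (1.44, adjusted p = 0.673) and Ankub1 (-1.12, adjusted p = 0.0544) were not.

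In Glb1KO, 15 of 23 disease-associated microglia genes rose, with Cd68 at 1.82 (SE 0.11), Trem2 raised 2.84-fold and Clec7a at 4.47. Of 45 lysosome genes 22 rose and 1 fell, with Ctss at 1.21 and Grn at 0.60. Complement genes rose in 7 of 12 cases, with C4b at 1.41 and C1qa at 1.21. Reactive astrocyte genes rose in 4 of 18 cases, which were Serpina3n (1.40), Gfap (1.27), Osmr (1.08) and Aspg (0.75). Cholesterol biosynthesis genes rose in 9 of 24 cases, with Stard4 at 0.52 and Fdft1 at 0.46 (adjusted p = 0.079 with an estimated correlation). Hindbrain and spinal neuron genes, markers of tissue at the rear of the brain, had a score of -1.66 in Glb1KO (SD 0.196, n = 5, exact p = 0.00794) and -1.23 in DKO. In Neu3KO, where the myelin score was -0.03, the hindbrain score was -0.96 (SD 1.24, exact p = 0.143). That list had 1 of 8 genes lower in Glb1KO, and its adjusted p = 0.0513 with an estimated correlation. Of 36 lists, 19 passed with the preset correlation and 10 with an estimated correlation, which were those of DKO vs WT without apoptosis and p53 targets. Among these, the ganglioside breakdown list includes Glb1 itself. Its score in Glb1KO was 0.04 (exact p = 0.167), and by the median of members it was higher than in WT by 0.157 (exact p = 0.00794). Of the 321 genes higher in Glb1KO, 293 were higher in DKO as well, and of the 405 lower genes 324 were lower in DKO. Independent lists of these sizes would share 44.8 and 61.1 genes, a value that leaves out the shared WT libraries. In 20 simulations without effects that shared the WT libraries 0 calls were shared, but at most 1 gene was called per comparison and direction, so this does not measure the part due to the shared libraries. With the WT libraries divided, which was added after the overlap was seen, a mean of 166 of 217 higher and 177 of 269 lower genes was shared, against 21 and 27.6 for independent lists. Across genes, which are not independent replicates, the changes in Glb1KO and DKO had a Pearson r = 0.659. Simulated groups without effects that shared the WT libraries gave r = 0.498, and the covariance was 0.0952, against 0.02 in that simulation. With the WT libraries divided between the comparisons the mean r was 0.428 and the covariance 0.0729, against 0.0021 and 0.00013 in simulations without effects. All WT libraries had identifiers starting with E, so dividing them left any difference tied to that letter in both comparisons. The simulations held no such difference, so its part in the shared calls and in r was not measured.

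**Figure D3:**
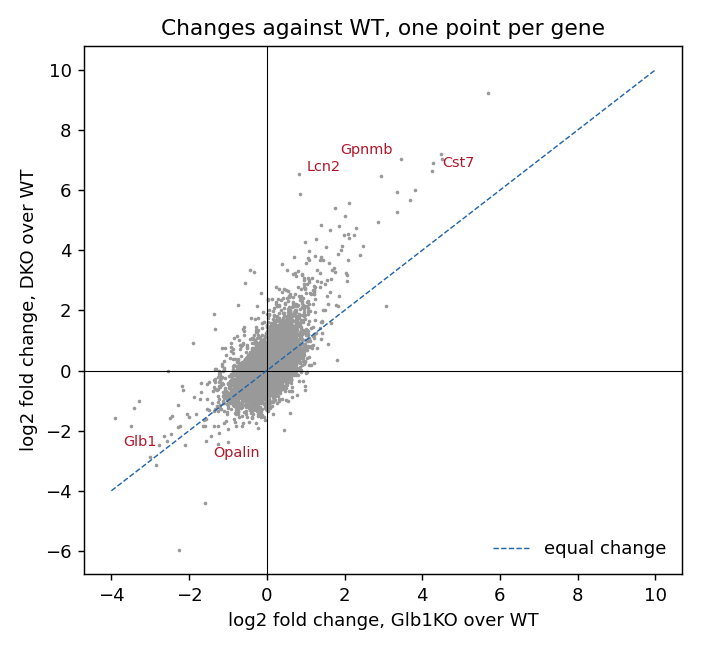
Fitted log2 fold changes over WT of 18336 genes in Glb1KO (horizontal axis) and DKO (vertical axis), with a point per gene and a dashed line of equal change. Gpnmb lies at 3.46 and 7.04, Opalin at -1.57 and -2.33, and the points share their WT libraries.

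Neu3KO was compared with WT, for the effect of losing Neu3 alone. No gene passed the threshold with edgeR, where the smallest adjusted p was 0.116 and 1105 genes had an unadjusted p under 0.05. DESeq2 called 2 genes, the fit without a filter on low counts 26 and the fit of these groups alone 3. Without WT replicate 1 or without WT replicate 2 the count was 1 in each case. The disease-associated microglia score was 0.12 in Neu3KO (SD 0.046, n = 5, exact p = 0.373), the lysosome score 0.035 (exact p = 0.159) and the myelin score -0.03 (exact p = 0.532). The immediate early gene score was -0.39 (exact p = 0.0159, adjusted exact p = 0.0372), and that of the unfolded protein and integrated stress response was -0.18 (exact p = 0.00794, adjusted exact p = 0.0207). By the median of members the former was -0.38 (exact p = 0.0159, adjusted exact p = 0.0398), and the latter did not pass, at -0.08 (exact p = 0.0794, adjusted exact p = 0.157). In these lists no member passed over all genes, while 3 of 13 and 1 of 20 passed when adjusted over the list alone. Of 36 lists, 17 passed with the preset correlation and 0 with an estimated correlation. Of the Neu3KO libraries, 1 shared the identifier letter of WT, so letter and genotype were largely confounded in this comparison.

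DKO was compared with Glb1KO, for the effect of losing Neu3 where Glb1 was already lost. Lcn2 was raised 51.5-fold (log2 5.69, SE 0.51, n = 5 per group), Ptx3 13.8-fold, Gpnmb 11.9-fold, Atp6v0d2 11.8-fold and Lilr4b 11.5-fold. The sizes for Lcn2, Lilr4b and Atp6v0d2 depended on the identifier letter. With it as a term and among libraries starting with E, the log2 changes of Lcn2 were 4.07 and 4.01. In the same order, those of Lilr4b were 2.88 and 2.76, and those of Atp6v0d2 were 6.88 and 6.83. The last rested on 1 read in 2 Glb1KO libraries. Those of Gpnmb (3.71 and 3.66) and Ptx3 (3.67 and 3.32) moved less. Abhd12b fell by 2.43 on the log2 scale (SE 0.30), and Cd6 (-1.46), Alpk2 (-1.45), Iltifb (-1.39) and Nrk (-1.36) were also lower. All 18 reactive astrocyte genes rose, with Serpina3n at 3.45 (SE 0.10), Gfap at 3.10 and Osmr at 2.61. Disease-associated microglia genes rose in 21 of 23 cases, with Cd68 at 2.07 and Lgals3bp at 1.86, lysosome genes in 35 of 45, with Grn at 1.38 and Ctsb at 0.97, and complement genes in 11 of 12, with C3 at 3.28 and C4b at 2.38. Interferon response genes rose in 10 of 23 cases and antigen presentation genes in 8 of 16. Pan-neuronal genes fell in 13 of 14 cases, with Vsnl1 at -0.40 and Snap25 at -0.28 (adjusted p = 0.0237 with an estimated correlation), and synaptic genes fell in 14 of 21 cases, with Shank3 at -0.38 (adjusted p = 0.0326 with an estimated correlation). Immediate early genes fell in 9 of 13 cases (adjusted p = 0.126 with an estimated correlation). The pan-neuronal score was lower than in Glb1KO by 0.268 (exact p = 0.00794). Lower scores were not confined to neurons, since the endothelial score differed by -0.19 (exact p = 0.00794). The inhibitory score differed by -0.135 (exact p = 0.0714) and that of pericytes and meningeal fibroblasts by -0.005 (exact p = 0.944). A dilution by RNA of other cells was not tested in this comparison.

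Of the myelin genes in DKO vs Glb1KO, 5 rose, 1 fell and 13 of 19 did not pass, with Cldn11 at 0.38 and Mbp at 0.26. The myelin score differed by 0.01, with a 95% interval from -0.15 to 0.17 and an exact p = 0.929 (n = 5 per group). With the identifier letter as a term the score was 0.20 higher in DKO than in Glb1KO (95% interval from 0.03 to 0.38), so the likeness of these groups depended on the letter. In all, 2879 genes passed the threshold, 1542 higher and 1337 lower. Of these, 417 changed at least 2-fold, with 356 higher and 61 lower. With the identifier letter as a term the count was 1203, and among libraries with identifiers starting with E it was 1837. Nrk lost its call in both, at -1.44 with the term (adjusted p = 0.0629) and -1.21 among the latter libraries (adjusted p = 0.656), which left 2 per group. Iltifb (-1.32, adjusted p = 0.191) and Gpnmb (3.66, adjusted p = 0.0566) lost it among the latter with folds close to the pooled ones. Of 36 lists, 21 passed with the preset correlation and 11 with an estimated correlation.

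DKO was compared with Neu3KO, for the effect of losing Glb1 where Neu3 was already lost. Lcn2 was raised 189-fold (log2 7.56, SE 0.62, n = 5 per group), Gpnmb 146-fold, Cst7 126-fold and Lilr4b 71.7-fold. The size for Lcn2 rested on few reads in Neu3KO, where its mean was 0.108 CPM. Atp6v0d2 had 2 reads in Neu3KO, and its ratio was 197 with a counting interval from 54.3 to 1640. Opalin fell by 2.53 on the log2 scale (SE 0.21), Abhd12b by 2.38, Slc5a1 by 1.49 and Alpk2 by 1.44, and Colq fell to 0.354 of its Neu3KO level. All 23 disease-associated microglia genes and all 18 reactive astrocyte genes rose, lysosome genes rose in 40 of 45 cases, and myelin genes fell in 18 of 19. In all, 4606 genes passed, 2263 higher and 2343 lower. Of these, 675 changed at least 2-fold, with 567 higher and 108 lower. Among libraries with identifiers starting with W, of which DKO had 3 and Neu3KO 4, the count of genes passing was 3699. Among these Lcn2 was at 8.24 and Lilr4b at 6.88 on the log2 scale, against 6.16 for Lilr4b over all libraries. Of 36 lists, 20 passed with the preset correlation and 11 with an estimated correlation.

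The interaction asked whether the change with Neu3 loss differed between mice with and without Glb1. Lcn2 had an interaction of 6.72 on the log2 scale (SE 1.45, n = 5 per group), Ptx3 of 4.02, Gpnmb of 3.73, Serpina3n of 3.44 (SE 0.14) and Steap4 of 3.31. The size for Lcn2 rested in part on low counts, with means of 0.232 CPM in WT and 0.108 CPM in Neu3KO. Negative interactions were those of Abhd12b (-2.83, SE 0.39), Cd6 (-1.73), Cox4i2 (-1.62), Crhr2 (-1.54) and Wnt9b (-1.49). Of the lists, disease-associated microglia had 18 of 23 genes with a positive interaction, reactive astrocytes 14 of 18, lysosome 27 of 45 and complement 8 of 12, and pan-neuronal genes had a negative interaction in 10 of 14 cases. In all, 1255 genes passed, 727 positive and 528 negative, with 288 of at least 2-fold. The call of Crhr2 was lost with the identifier letter as a term (-1.32, adjusted p = 0.0619), and that of Lcn2 without WT replicate 4 (adjusted p = 0.0517). Of 36 lists, 20 passed with the preset correlation and 10 with an estimated correlation.

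**Figure D4:**
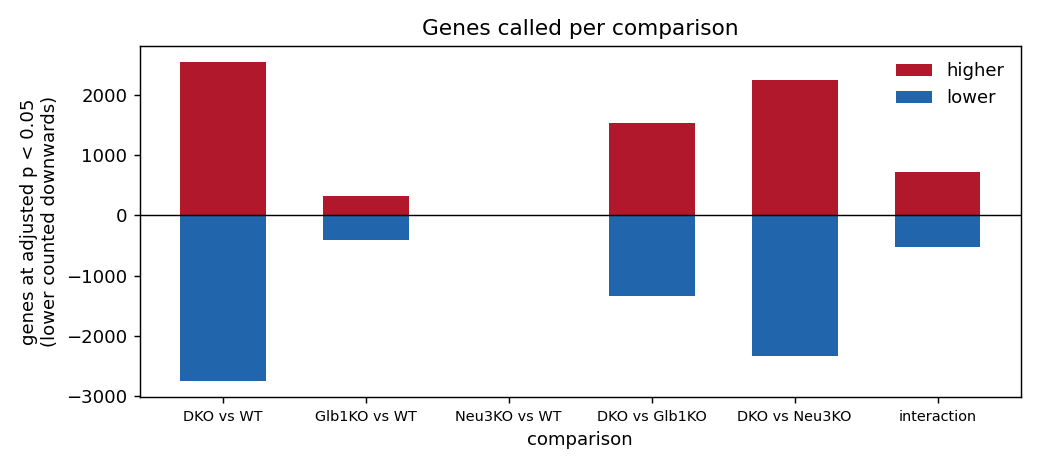
Number of genes at an adjusted p under 0.05 (vertical axis) in each comparison (horizontal axis), with higher genes as bars upwards and lower genes as bars downwards. DKO vs WT had 5323 genes, Glb1KO vs WT 726 and Neu3KO vs WT 0.

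Genes within 20 Mb of Glb1 or Neu3 were examined apart, since such genes can carry the haplotype of the strain in which an allele was made. Near Glb1, Parp3 (1.48, SE 0.13) and Tgfbr2 (0.78) rose and Rbm15b (-0.51) fell in DKO vs WT, and Fbxw15 (-2.24, SE 0.33) and Mobp (-0.73) fell in Glb1KO vs WT. Near Neu3, Ctsc (1.76, SE 0.13) and Ucp2 (1.22) rose and Ccp110 (-0.52) fell in DKO vs WT. In DKO vs WT 26.6% of 379 genes near Glb1 and 26.8% of 343 genes near Neu3 passed, against 29.1% of 17612 genes elsewhere (Fisher's exact p = 0.304 and 0.368). In Glb1KO vs WT the shares were 3.96% near Glb1 and 4.96% near Neu3, against 3.93% elsewhere (Fisher's exact p = 0.894 and 0.326). In a window of 40 Mb around Glb1, fewer genes passed in DKO vs Neu3KO than elsewhere (21.2% against 25.2%, Fisher's exact p = 0.0448). That value was not adjusted for the windows, loci and comparisons tested, and no other was under 0.05. Windows of 20 and 10 Mb gave Fisher's exact p = 0.0938 and 0.28, so no conclusion is drawn from it. Genes are not independent of each other in these tests.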

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

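Of the tests in this part, those of the identifier letter for myelin, of precursor against myelin genes, of granule against Purkinje cell genes, and of excitatory against inhibitory genes were chosen after the results were seen, and the counts of splits with an estimated correlation were added after the first split counts of lists had been seen.

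Arbitrary splits of the same libraries into groups of 5 were fitted in the same way, 100 per comparison with the genotypes included. For genes, 1 of 100 splits, the genotypes themselves, gave as many calls in DKO vs WT (5323, highest other 366), Glb1KO vs WT (726, highest other 166), DKO vs Glb1KO (2879, highest other 201) and DKO vs Neu3KO (4606, highest other 1363). A share of 1 in 100 is the smallest these splits can give, and it argues against chance alone. It does not separate genotype from the identifier letter, which was uneven over the genotypes. In the interaction, with all labels shuffled, 2 of 100 gave as many, a share under 0.05, and another split gave 1544 against 1255. That shuffle also removed the effect of each knockout alone. It therefore does not test the interaction by itself, and no conclusion is drawn from it. In Neu3KO vs WT all 100 splits gave at least 0 genes and the highest other gave 5. For lists with the preset correlation, 8, 6, 9, 15 and 7 of 100 splits gave as many in DKO vs WT (23, highest other 25), Glb1KO vs WT (19, 20), DKO vs Glb1KO (21, 24), DKO vs Neu3KO (20, 25) and the interaction (20, 22), so chance was not excluded for those counts. In Neu3KO vs WT 1 of 100 did (17, highest other 15). With an estimated correlation and adjustment within each comparison, the genotypes gave 11, 11, 11, 12 and 10 lists in the same 5 comparisons, in each of which 1 of 100 splits gave as many and the highest other gave 1. In Neu3KO vs WT they gave 0 lists, as many as or fewer than all 100 splits, of which the highest gave 2.

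Of 19 myelin genes 18 fell in Glb1KO and in DKO (adjusted p = 0.000354 and 0.0158 with an estimated correlation), while of 8 hindbrain genes 1 and 3 fell (adjusted p = 0.0513 and 0.333 with an estimated correlation). With the hindbrain score as a covariate over 20 libraries, the myelin score still differed from WT by -0.751 in Glb1KO (SE 0.097, before -0.884). In DKO it differed by -0.775 (SE 0.086, before -0.874). The slope on the hindbrain score was 0.081 (SE 0.041), and the hindbrain scores of Glb1KO and DKO did not overlap those of WT. A score of 8 genes measures tissue imperfectly and can adjust too little, so less hindbrain tissue stayed open. The myelin score fell further than the precursor score, by -0.652 in DKO (exact p = 0.00794, adjusted exact p = 0.0119, n = 5 per group), which argues against an equal loss of the whole lineage, although Sox10, Olig1 and Olig2 also fell. Without WT replicate 1, 18 of 19 myelin genes were still called in Glb1KO, and with the identifier letter as a term the score differed from WT by -0.942 in Glb1KO (SE 0.074) and by -0.737 in DKO (SE 0.067), which argues against that library and the letter as the whole cause, although 2 libraries per group shared the letter of WT. An effect of Glb1 loss on mature oligodendrocytes is a hypothesis, and age and disease stage stayed open and were not tested.

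Of the 11 cerebellar genes 5 fell in DKO, among them Pcp2, Car8 and Itpr1 of Purkinje cells, the output neurons of the cerebellum, and the list's adjusted p = 0.486 with an estimated correlation. In a first test, 7 members other than the granule cell genes Gabra6, Cbln1, Cbln3 and Fat2 fell further than those 4 by -0.733 (exact p = 0.00794) and than the pan-neuronal score by -0.422 (exact p = 0.0476, adjusted exact p = 0.0476), but the 7 included Neurod1 and Zic1 of granule cells. The genes were reassigned after that value was seen, and Pcp2, Car8, Itpr1 and Gng13 then fell further than 6 granule cell genes by -0.885 (exact p = 0.00794, adjusted exact p = 0.0119, n = 5 per group). The change of the 6 granule cell genes was -0.06 (95% interval from -0.317 to 0.197), although Zic1 was called at -0.42. That of the 4 others was -0.945 (from -1.315 to -0.576). The 4 were grouped around genes seen to fall, and En2 was left out of both groups, so their fall may be overstated at -0.945. Their greater fall was partly fixed by that choice, so it does not decide against less cerebellum or an even dilution. The granule interval leaves room for a fall to -0.317, and age and disease stage also stayed open.

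Of the pan-neuronal genes 8 of 14 fell in DKO, of the synaptic genes 12 of 21 and of the excitatory genes 9 of 13 (adjusted p = 0.131, 0.125 and 0.307 with an estimated correlation), and the inhibitory score was -0.032 (exact p = 0.508). Excitatory genes fell further than inhibitory genes by -0.171 (exact p = 0.0476, adjusted exact p = 0.0476, n = 5 per group). That contrast was chosen after both scores were seen, so it does not decide against an even dilution by RNA of other cells. The 621 genes raised at least 2-fold took 2.26% of counts in DKO and 0.576% in WT. Without them the median pan-neuronal change was -0.148 (SE of the mean 0.061 over genes), against -0.17 with them. Shares this small could shift other genes only slightly, so that refit could hardly have come out otherwise. The small shares themselves argue against those genes taking the counts as the whole cause. An even dilution, a change in the share of neurons and a change within neurons stayed open.

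A library stood apart from the others of its group in 18 of 332 groups of 5 examined, close to the 1 in 20 that chance gives. WT replicate 1 accounted for 4 of these and stood apart as a whole, with a chi-square per degree of freedom of 21.9 to 29.8 against the other WT libraries, where all other pairs within a group had 3.44 to 14.2, and a second principal component of 49.9, where the other libraries lay between -18.1 and 13.8. Without it 4838 genes were called in DKO vs WT and 596 in Glb1KO vs WT. It had an rRNA share of 1.27% (nearest 0.378%), a mitochondrial share of 2.45% (nearest 3.74%), a resting astrocyte score of -0.184 and a mitochondrially encoded score of -0.678. WT replicate 3 had a striatal score of 0.115, Neu3KO replicate 4 a resting astrocyte score of 0.156, and Glb1KO replicate 4 a mitochondrially encoded score of 0.006. In DKO, replicate 4 had an interferon score of 0.743, replicate 5 a border-associated macrophage score of 1.813 and replicate 1 a pituitary score of 2.295. On the log2 CPM scale, Alpk2 was at -1.519 in DKO replicate 2, Atp6v0d2 at 1.44 and Egr2 at 1.44 in DKO replicate 5, Colq at 0.554 in Neu3KO replicate 3, Slc6a5 at 3.187 in Glb1KO replicate 2, and Arc at 7.092, Gpnmb at 4.68 and Npas4 at 3.52 in Glb1KO replicate 5.

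The change with Neu3 loss differed between mice with and without Glb1 for 1255 genes, by the interaction test. Named genes among them were Lcn2 (6.722), Ptx3 (4.017), Gpnmb (3.734), Serpina3n (3.439), Steap4 (3.309), Abhd12b (-2.825), Cd6 (-1.73), Cox4i2 (-1.616), Crhr2 (-1.537) and Wnt9b (-1.485). Lists that passed with the preset and with an estimated correlation had median interactions of 1.263 (disease-associated microglia), 2.055 (reactive astrocytes), 0.439 (lysosome), 0.297 (ganglioside breakdown), 0.45 (interferon), 1.145 (complement), 0.531 (antigen presentation), 0.822 (cytokines), -0.261 (pan-neuronal) and -0.246 (synaptic). Lists that passed with the preset correlation alone had medians of 0.327 (homeostatic microglia), 0.23 (resting astrocytes), -0.303 (excitatory neurons), -0.369 (immediate early genes), -0.139 (ganglioside synthesis), 0.399 (proliferation), -0.439 (mitochondrially encoded), -0.241 (endothelial cells), -0.129 (cerebellar neurons) and 1.038 (hindbrain neurons). The mitochondrially encoded value drew in part on WT replicate 1, whose score of -0.678 stood apart from the nearest WT score of 0.061.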

How the results depend on the processing

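The alternatives that used only libraries with identifiers starting with E or W were chosen after the data were seen. With the identifier letter as a term the gene counts were 3363 in DKO vs WT, 315 in Glb1KO vs WT and 1203 in DKO vs Glb1KO, and among libraries starting with E they were 2370, 291 and 1837, the latter with fewer samples. With a minimum of a 2-fold change they were 782, 99, 417, 675 and 288 in DKO vs WT, Glb1KO vs WT, DKO vs Glb1KO, DKO vs Neu3KO and the interaction. Neu3KO vs WT gave 26 genes without a filter, 3 in a fit of these groups alone and 2 with DESeq2. With an estimated correlation 11, 10, 0, 11, 11 and 10 lists passed in DKO vs WT, Glb1KO vs WT, Neu3KO vs WT, DKO vs Glb1KO, DKO vs Neu3KO and the interaction. The similarity of the DKO and Glb1KO changes went from r = 0.659 to 0.428 with divided WT libraries. Directions reversed for Pmch in DKO vs Glb1KO (-0.27 to 0.97 with the letter term), Avp in DKO vs WT (-0.05 to 0.62 in E libraries), Il33 in DKO vs WT (-0.265 to 0.018 in E libraries) and Hmgcs1 in DKO vs Neu3KO (0.01 to -0.26 in W libraries). The cause was not tested for the changes with the letter term, the filter, DESeq2 and these reversals.

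Without each library in turn, the gene counts ran from 4449 to 5349 in DKO vs WT, 549 to 833 in Glb1KO vs WT, 0 to 1 in Neu3KO vs WT, 2309 to 3031 in DKO vs Glb1KO, 3792 to 4685 in DKO vs Neu3KO and 981 to 1341 in the interaction, and list counts ran from 21 to 24, 16 to 21, 12 to 20, 20 to 21, 20 to 21 and 17 to 23. The replicate numbers did not pair libraries across genotypes, since 0 of 30 same-number pairs had r over 0.1. With the replicate number as a block, the counts were 5207, 685, 0, 2774, 4448 and 1136 genes. Counting depth limited genes such as Neu3, at 35 to 100 reads per library, and a term for sex could not be fitted.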

Other observations

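No test in this part was chosen after its result was seen, and the lists of DKO vs WT not given with that comparison are given here.

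Border-associated macrophage genes rose in 6 of 8 cases in DKO vs WT, with Ms4a7 at 4.54 (SE 0.42, n = 5 per group) and Mrc1, a mannose receptor, at 1.68 (adjusted p = 0.00868 with an estimated correlation). Apoptosis and p53 target genes rose in 8 of 13 cases and fell in 1, with Fas at 1.51, and Phlda3 fell by 0.48 on the log2 scale (adjusted p = 0.0276 with an estimated correlation). Proliferation genes rose in 4 of 10 measured cases, with Cdk1 at 2.71 and Top2a at 1.49 (adjusted p = 0.134 with an estimated correlation). Leukocyte genes rose in 3 of 5 measured cases, with Ptprc at 1.85 and S100a8 at 3.27 (adjusted p = 0.214 with an estimated correlation), and 13 members of that list, including Cd3e, were too low to test. Resting astrocyte genes rose in 9 of 14 cases and fell in 1, with Aqp4 at 1.60, and Slc1a2 was at -0.01 (adjusted p = 0.136 with an estimated correlation). Cholesterol biosynthesis genes rose in 12 of 24 cases, with Acat2 at 0.69 (adjusted p = 0.284 with an estimated correlation). Ganglioside synthesis genes rose in 1 and fell in 6 of 16 cases, with St8sia5 at -0.50 (adjusted p = 0.23 with an estimated correlation). Excitatory neuron genes fell in 9 and rose in 1 of 13 cases, with Grin2b at -0.41 (adjusted p = 0.307 with an estimated correlation), and hindbrain genes fell in 3 of 8 cases (adjusted p = 0.333 with an estimated correlation).

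The other lists did not pass in DKO vs WT. Their adjusted p with the preset correlation was 0.803 for inhibitory neurons, where Vip rose by 0.56, 0.369 for the unfolded protein and integrated stress response, where Atf3 was at 1.42 and Atf4 at -0.41, and 0.767 for mitochondrially encoded genes. It was 0.363 for endothelial cells, 0.322 for pericytes and meningeal fibroblasts, 0.541 for choroid plexus and ependyma, 0.431 for red blood cells and 0.743 for striatal neurons. It was 0.201 for hypothalamic neuropeptides, 0.63 for pituitary, 0.939 for olfactory bulb neurons and 0.966 for Schwann cells and peripheral nerve, where Pmp22 rose by 0.70 and Sox10 fell by 0.82 on the log2 scale.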
